A study of Mus musculus with 2 samples.

How the data were processed

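The measurements are single-cell RNA counts of cultured mouse hematopoietic stem cells in 2 libraries, 1 of cells kept for 48 h in RO-3066 and 1 of cells kept in DMSO, grouped by the treatment given in the labels. Per the labels, the libraries were made with the 10x Genomics single-cell 3' gene expression workflow. The authors deposited a matrix of UMI counts per gene and barcode for each library, with no normalization. Per the submitters' processing notes, Cell Ranger 5.0.1 and the mouse genome build mm10 were used, while the deposited matrix headers name Cell Ranger 7.1.0; which version made the counts, the annotation release and whether intron reads were counted are not given in the sources used here. Reads of genes that overlap or of near-identical copies, such as histone and globin genes, can be split or lost in such counting. The 32285 gene identifiers of the deposited matrices were looked up in GENCODE vM21 (mm10); 32158 were found, and gene coordinates are from that annotation. Where identifiers shared a symbol, the one with the most UMIs kept it and the other 40 were named by identifier, a rule set after first results had been seen, which brought Ddit3 and Aldoa into their lists.

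Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. This left out 26 DMSO and 84 RO-3066 barcodes. Likely doublets were scored in each library by the share of simulated doublets among 50 neighbours and called at 0.8% per 1000 barcodes, which removed 302 DMSO cells (4.92%) and 118 RO-3066 cells (3.11%). The kept cells held 174783653 and 163272308 UMIs, and the intervals given with folds and shares show their counting error. For the floor of detection, 3 counts of the library total were used.

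UMIs were summed over kept cells and expressed as CPM. The log2 ratio of a gene is that of CPM plus a pseudocount of 1, RO-3066 over DMSO. With 1 library per group there was no test, and genes were counted by a fold of 2 among those with at least 20 CPM in either library. Intervals of folds are exact conditional intervals of the ratio of Poisson counts, and those of shares exact Clopper-Pearson intervals, at a confidence of 95%. Both cover counting error only. Intervals of list medians are exact binomial intervals of a median over member genes. That of a cluster's median UMIs is taken over its cells in the same way, with the median it is set against held fixed. Gene lists were written before the data were examined, 33 in all, except a list of hypoxia-inducible factor targets written after. A list's median was taken over members with at least 5 CPM and set against 10000 random lists of the same size matched in 20 bins of mean expression; the percentile describes these 2 libraries and is no p-value. The ribosomal protein list was taken by a pattern of symbols that also admits Rpl7l1 and Rps6ka1. Genes named in the text follow a rule fixed beforehand: a set of cell cycle, p53, megakaryocyte and stem cell genes, the 10 highest and 10 lowest ratios among genes with at least 50 CPM without unnamed gene models, mitochondrial and ribosomal protein genes, and in each list the 3 members with the largest ratio among those with at least 20 CPM. A gene that this rule takes is not reported here. Other genes named are leading genes of clusters, members of tested lists, or are said to have been chosen after their values were seen.

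Phase scores (scanpy 1.11.5) were computed on cells thinned to 10000 UMIs, leaving out 84 DMSO and 124 RO-3066 cells with fewer, and a cell with neither score above 0 was called G1. For clusters, 2000 variable genes without cell cycle, histone, ribosomal and mitochondrial genes, 30 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.8 were used, without integration of the libraries. Clusters were named from marker lists fixed beforehand. A median log2 ratio of at least 1 for the megakaryocyte list, a limit set after the data were seen, defined megakaryocyte-like clusters when shares were counted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

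The alternatives tried were median-ratio scaling, equal weight per cell, thinned cells, doublets kept, all barcodes, a mitochondrial limit of 5%, phases given equal weight, cells called G1, a pseudocount of 5, other minimum levels of expression, other depths of thinning, score limits and cluster resolutions, cell cycle genes kept in clustering and clustering of DMSO cells alone. Added after the data were seen were leaving out the megakaryocyte-like cells, leaving out a p53-target-rich cluster, cells of 15000 to 40000 UMIs, the middle 50% of cells by UMIs of each library, and clustering without the megakaryocyte list. The calculation was tested on simulated data: Poisson counts for 8931 genes at the depths of both libraries, with 200 genes changed. All 100 genes changed 3-fold and 0 of the genes changed 1.5-fold were counted as 2-fold changed, 0 of 8691 unchanged genes were, the intervals held the true fold in 95.1% of genes, and a list shifted by 0.38 (log2) gave a median of 0.37. The simulated counts hold counting error only and took genes from 5 CPM in DMSO. They check the calculation and say nothing of spread between cells or between cultures.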

Results

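Mouse hematopoietic stem cells, labelled as coming from blood, were kept in suspension culture for 48 h in RO-3066 or in its vehicle, dimethyl sulfoxide (DMSO), and then profiled by droplet single-cell RNA sequencing of transcript 3' ends. The labels name the compound only as RO-3066 and state neither its target nor its dose. A known inhibitor of Cdk1 that holds cells at the border of G2 and M has the similar name RO-3306; whether it is meant is not settled by the labels, which leaves open how the phase calls and the values of Cdk1 and Plk1 given here should be read. The series title places the work in DNA damage and the formation of megakaryocytes, the cells that shed platelets. There were 2 libraries, 1 per treatment, so no difference below has a replicate check and none was tested across samples. Intervals of folds and shares are 95% exact intervals that cover counting error only. Those of list medians show the spread over member genes, and that of a cluster's median UMIs the spread over its cells. The DMSO library held 6160 barcodes with 188022321 UMIs (unique molecular identifiers, each counting 1 captured transcript) and the RO-3066 library 3882 barcodes with 171821236 UMIs. After filtering, 5832 DMSO cells had a median of 24009.5 UMIs and 4763.5 genes, and 3680 RO-3066 cells a median of 34656 UMIs and 5703.5 genes, a ratio of 1.44 for UMIs. The female-specific transcript Xist stood at 512 CPM (UMI counts scaled to a common library total) in DMSO and 547 CPM in RO-3066.

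The question here was which genes differ between cells cultured with the compound and with vehicle. Of 5761 genes with at least 20 CPM in either library, 34 were at least 2-fold higher and 39 at least 2-fold lower in RO-3066, and 5438 lay within 1.5-fold. Apart from unnamed gene models, the highest ratios among genes of at least 50 CPM were those of Apoe, Lst1, Slc6a13, Treml1, Pdzk1ip1, Zbtb20, Cotl1, Hbb-bt, Blvrb and Cdkn1a. Apoe, which encodes the lipid carrier apolipoprotein E (chromosome 7, 19696109 to 19699188, mm10), was at 122 CPM in RO-3066 against 28.9 in DMSO, 4.23-fold higher (4.10 to 4.36). The lowest were those of Hist1h2bc, Bnip3, Hist1h1b, Mt1, Hist1h1e, H1f0, Ifitm1, Slc16a3, Hist1h2ae and Hist1h1d, of which 6 encode histones and Mt1 a metallothionein. In cells called G1 Slc6a13 was lower (log2 -0.077). Bnip3, a mitophagy receptor (chromosome 7, 138890836 to 138909519), had 26.0 CPM in RO-3066 and 92.1 in DMSO, 0.282-fold (0.273 to 0.292). With scaling by the median ratio over genes the counts were 24 higher and 45 lower, so that 34.8% in place of 46.6% of these genes were higher, and the median log2 ratio of all genes compared was -0.16 in place of -0.06. The balance depended on the minimum level, with 201 higher and 65 lower (75.6% higher) without one, 121 and 58 (67.6%) at 5 CPM and 5 and 13 (27.8%) at 100 CPM, and it was 102 and 67 (60.4%) in cells called G1. With every cell at the same weight the counts were 22 and 23.

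Genes of megakaryocytes and platelets were higher in the RO-3066 library. Of 40 members of this list with at least 5 CPM, 15 were at least 1.5-fold higher, none was at least 1.5-fold lower and 25 lay between, with a median log2 ratio of 0.44, at percentile 100 of 10000 random lists matched on expression. Treml1, a receptor stored in platelet granules (chromosome 17, 48359916 to 48367176), was 2.72-fold higher (2.63 to 2.81), at 79.1 against 29.1 CPM. Nrgn was 1.89-fold, Mmrn1 1.96-fold, the integrin gene Itga2b (chromosome 11, 102453297 to 102470122) 1.56-fold and the von Willebrand factor gene Vwf 1.54-fold higher, while Gp9 and Gp1bb, which encode parts of the platelet receptor for that factor, were 1.46-fold and 1.22-fold higher. Pf4, platelet factor 4 (chromosome 5, 90772435 to 90773383), was by far the most abundant member and was lower, at 4240 CPM against 5131 in DMSO (0.826-fold, 0.824 to 0.829), although it was higher by 0.058 (log2) with the phases given equal weight and by 1.51 in cells called G1. Among 19 megakaryocyte transcription factors the median was 0.20 (-0.03 to 0.36 over members, percentile 99.9). Gfi1b was at 1.69-fold, Gata1 at 1.44-fold, Nfe2 at 1.38-fold and Fli1 at 0.963-fold. Among cells of 15000 to 40000 UMIs, a range chosen after the data were seen that held 80.3% of DMSO but 48.9% of RO-3066 cells, the megakaryocyte median was -0.037 and Treml1 (-0.13), Vwf (-0.16), Gp1bb (-0.73) and Gata1 (-0.83) were lower in RO-3066 (log2), and among cells called G1, 86 of them in RO-3066, it was 1.07.

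**Figure D1:**
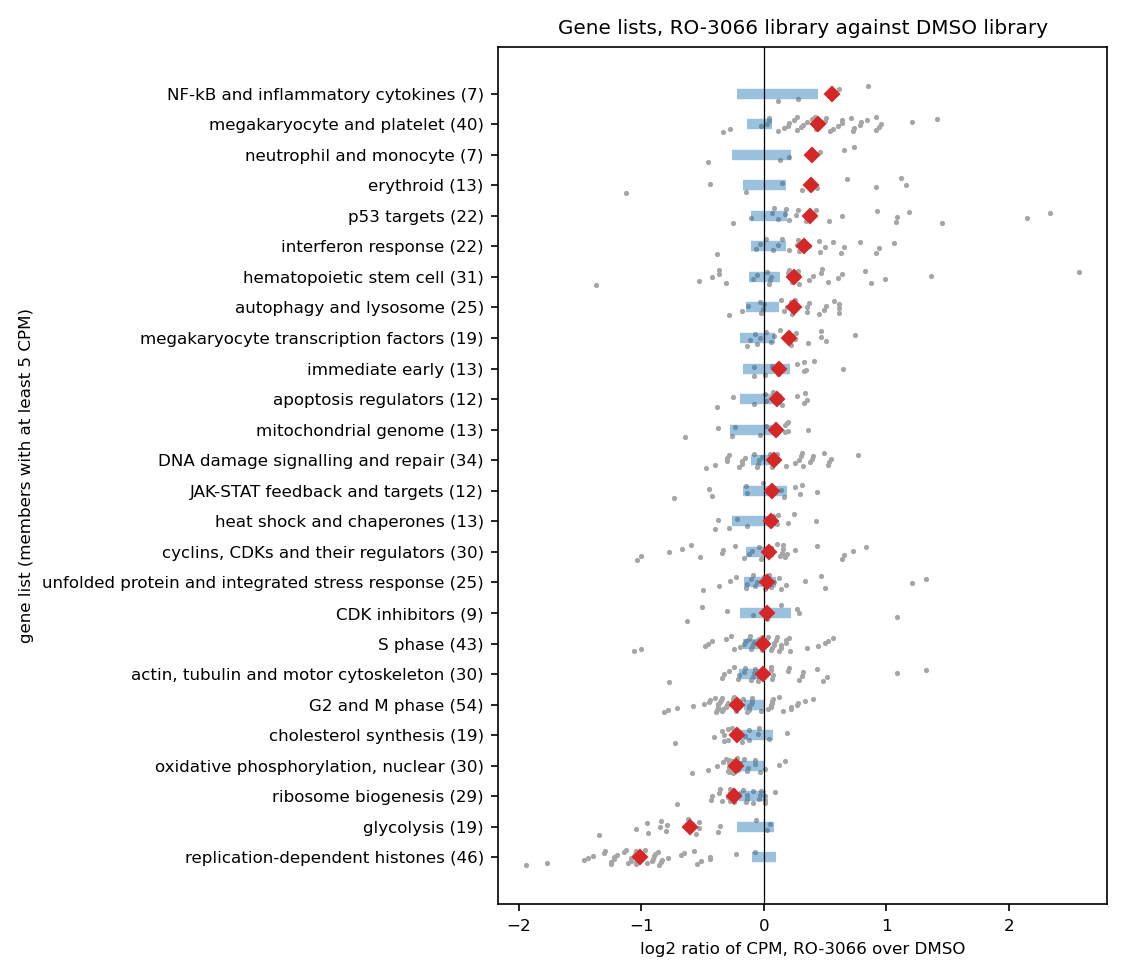
Log2 ratio of CPM in the RO-3066 library over the DMSO library (horizontal axis) for members of the gene lists with at least 7 members measured, the number measured in parentheses. Grey points are genes, red diamonds list medians and blue bars the middle 95% of medians of 10000 matched random lists; replication-dependent histones (-1.01) and glycolysis (-0.61) lie lowest, and megakaryocyte and platelet genes (0.44) lie to the right of their bar.

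The share of single cells with a high megakaryocyte score was also compared. The score, the mean log expression of the same list in cells thinned to 10000 UMIs, was above the 90th percentile of DMSO cells in 10.0% of 5748 DMSO cells (9.24 to 10.8) and in 18.7% of 3556 RO-3066 cells (17.4 to 19.99). Within 0.02 of this limit lay 118 DMSO and 95 RO-3066 cells, and 84 and 124 cells had too few UMIs to be scored. Without thinning, the RO-3066 share was 19.5%. By phase call, high scores were held by 11.8% (10.7 to 12.97) in DMSO and 21.4% (19.9 to 22.9) in RO-3066 among cells called G2M, and by 8.19% (7.11 to 9.39) and 9.04% (6.999 to 11.4) among cells called S; whether these gaps differ was not tested. Median scores were 0.221 and 0.262. A high score marks the top of a range and no cell type, and RNA free in the droplets counts toward it in both libraries.

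Targets of the tumour suppressor p53 were higher in RO-3066. Of 22 members, 8 were at least 1.5-fold higher and none at least 1.5-fold lower, with a median of 0.38 (percentile 100). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), was 2.17-fold higher (2.09 to 2.25), at 51.0 against 23.5 CPM. Ccng1 was 1.58-fold and the pro-apoptotic gene Bbc3 1.47-fold higher, while Mdm2, which encodes the ubiquitin ligase of p53, was 1.14-fold higher. Without the cells of a small RO-3066 cluster led by p53 targets, left out after the data were seen, the list median was 0.19 and the Mdm2 ratio turned to -0.032 (log2), and over the other alternatives the list median reached 0.97, in cells called G1. DNA damage signalling and repair genes had a median of 0.08 (percentile 91.2), with 1 of 34 members, Rad54l at 1.75-fold, beyond 1.5-fold, and Brca2 at 1.47-fold. Among 9 CDK inhibitor genes the median was 0.02, with Cdkn1b at 0.697-fold and Cdkn2d at 0.808-fold (log2 0.76 in cells called G1). Apoptosis regulators had a median of 0.11 (percentile 93.6).

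Genes of the G2 and M phases were slightly lower in summed expression, although a larger share of cells was called G2M. Of 54 genes of these phases 3 were at least 1.5-fold lower and none at least 1.5-fold higher, with a median of -0.22 (percentile 0.02): Hmmr stood at 0.566-fold, Pimreg at 0.572-fold, and Hmgb2, a chromatin protein gene, at 0.611-fold. Top2a was at 0.757-fold and Mki67 at 0.858-fold. In cells called G1 the list median was 0.20, Top2a was higher by 0.86 and Hmmr by 0.42 (log2). The list median was -0.0037 when every cell had the same weight and 0.013 when cells were thinned to 10000 UMIs, and Mki67 was higher under both, by 0.16 (log2). On cells thinned to 10000 UMIs, 56.4% of DMSO cells (55.1 to 57.7) and 78.3% of RO-3066 cells (76.9 to 79.6) were called G2M, 40.1% (38.9 to 41.4) and 19.3% (18.0 to 20.6) S, and 3.46% (3.005 to 3.97) and 2.42% (1.94 to 2.98) G1. Among cells called G2M the median G2M score was 0.446 in DMSO and 0.303 in RO-3066. The S and G2M scores lay within 0.05 of each other in 7.59% of DMSO and 11.2% of RO-3066 cells. Without thinning, G2M calls were 57.0% and 82.0%. Because the share of G2M calls and the summed expression of G2 and M phase genes went opposite ways, no order of the libraries in cycling is read from either, and RNA free in the droplets, which the phase calls also read, stays open. S phase genes had a median of -0.00 (percentile 95.5), with Rfc2 at 1.49-fold (log2 -0.13 in cells called G1), Gins2 at 1.45-fold and Pcna at 0.990-fold.

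**Figure D2:**
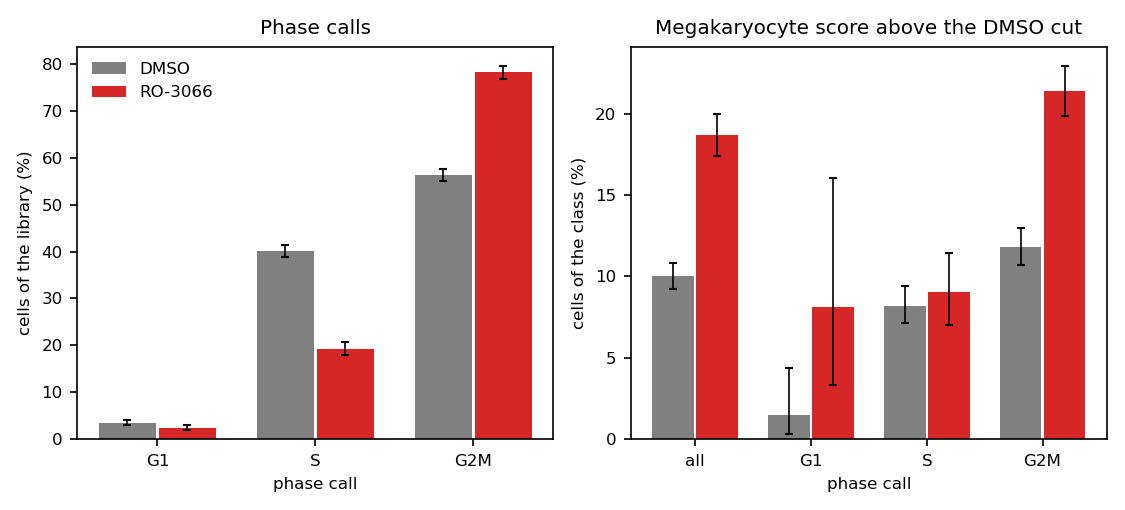
Left, percent of cells of each library called G1, S or G2M; right, percent of cells with a megakaryocyte score above the 90th percentile of DMSO cells, over all cells and by phase call. Bars are DMSO (grey) and RO-3066 (red) with 95% exact binomial intervals; G2M calls are 56.4% and 78.3%, and high scores 10.0% and 18.7%.

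Individual cell cycle regulators went both ways. Cdk1, the kinase that drives entry into mitosis (chromosome 10, 69335146 to 69352938), was 1.12-fold higher (1.10 to 1.13; log2 -0.095 among cells of 15000 to 40000 UMIs) and its partner Ccnb1 1.04-fold, while Ccna2 was at 0.695-fold, the mitotic kinase gene Plk1 at 0.580-fold and Ccne2, a cyclin of S phase entry, at 0.492-fold. Pkmyt1, which encodes a kinase that inhibits Cdk1, was 1.70-fold higher. Of 30 cyclins, CDKs and their regulators 4 were at least 1.5-fold higher and 5 at least 1.5-fold lower, with a median of 0.04 (percentile 91.9). Replication-dependent histone genes, a set taken by a pattern of symbols that also admits the replication-independent H1f0, stood apart: 39 of 46 were at least 1.5-fold lower, none higher, with a median of -1.01 (percentile 0). Hist1h1b, a linker histone gene (chromosome 13, 21779883 to 21780625), was at 0.292-fold (0.289 to 0.294), with 417 against 1429 CPM. Histone transcripts took 0.521% of UMIs in DMSO and 0.213% in RO-3066. Most such transcripts lack a poly(A) tail, so the counts cover only those that were captured. The histone median was -0.44 within cells called G1 (29 members), -0.96 within those called S and -1.12 within those called G2M. In cells called G1 Plk1 was higher, by 0.29 (log2).

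Glycolysis genes were lower in RO-3066. Of 19 members 11 were at least 1.5-fold lower and none at least 1.5-fold higher, with a median of -0.61 (percentile 0). The lactate exporter gene Slc16a3 was at 0.384-fold (0.371 to 0.398), the pyruvate dehydrogenase kinase gene Pdk1 at 0.475-fold and the phosphofructokinase gene Pfkl at 0.512-fold. Nuclear genes of oxidative phosphorylation had a median of -0.23 (percentile 2.10), with Cycs at 0.666-fold and Cox5b at 0.727-fold. Ribosome biogenesis genes had a median of -0.24 (percentile 0.31), with Pno1 at 0.605-fold and nucleolin, Ncl, at 0.746-fold, and cholesterol synthesis genes a median of -0.22 (percentile 1.35), with Hmgcs1 at 0.601-fold. In contrast, ribosomal protein genes had a median of 0.15 (percentile 100) and took 33.0% of UMIs against 29.5% in DMSO, and Rplp1 was 1.54-fold higher.

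Genes that mark hematopoietic stem cells had a median of 0.25 (percentile 99.99). The score of this list per cell hardly differed at its median, 0.248 in DMSO and 0.249 in RO-3066. It was above the 90th percentile of DMSO cells in 9.99% of DMSO and 12.9% of RO-3066 cells. Of 31 members 7 were at least 1.5-fold higher, 1 at least 1.5-fold lower and 23 between. Pdzk1ip1 was 2.62-fold higher (2.55 to 2.70) and the endothelial adhesion gene Esam 1.59-fold, whereas Ifitm1, an interferon-inducible membrane protein gene (chromosome 7, 140967221 to 140969825), was at 0.386-fold (0.383 to 0.388), with 549 against 1424 CPM. Hlf stood at 1.18-fold, Mecom at 1.04-fold and Procr, at 4.27 against 4.58 CPM, at 0.933-fold (0.842 to 1.03). Among 13 erythroid genes the median was 0.39 (-0.14 to 0.91 over members, percentile 99.99). The globin gene Hbb-bt was 2.25-fold and Blvrb 2.19-fold higher, but the transferrin receptor gene Tfrc was at 0.445-fold (0.426 to 0.465), and Klf1 had 2.93 against 1.02 CPM. In cells called G1, 86 of them in RO-3066, the erythroid median was -0.14 and Hbb-bt (-0.43), Nkg7 (-0.37) and Lyz2 (-0.065) were lower, and among cells of 15000 to 40000 UMIs Klf1 (-0.073) and Nkg7 (-0.38) were (log2). Of the neutrophil and monocyte list 7 of 33 genes were measured, with a median of 0.39 (-0.45 to 0.73 over members, percentile 99.9). Nkg7 was at 1.68-fold and Lyz2 at 1.59-fold, while Prtn3, named after its values were seen, was lower at 70.2 against 96.4 CPM (log2 -0.45). Mpo was at 0.253-fold (0.151 to 0.406), with 0.135 against 0.532 CPM. The mast cell, basophil and eosinophil (-0.03, percentile 39.9), lymphoid (0.34, percentile 87.8; -0.028 in cells called G1) and dendritic cell (0.07, percentile 65.4) lists had 3 genes measured each, and of the endothelial and stromal list fewer than 3 were measured.

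Clustering of both libraries together largely separated them: of 13 clusters, 12 drew over 90% of their cells from a single library, and such a cluster may be that library and no cell type. A cluster with 175 of its 182 cells from DMSO was megakaryocyte-like, with Clec1b, Ppbp and Pf4 among its 10 leading genes. A cluster with 15.2% of RO-3066 cells had a megakaryocyte list median of 1.42 (log2 against all other cells) but none of the list among its 10 leading genes. Since the genes that define these clusters differ between the libraries, their sizes are not compared; DMSO cells were clustered alone instead and each RO-3066 cell was given the cluster most common among its nearest DMSO cells. When the megakaryocyte list was left out of that clustering, a step chosen after the data were seen, clusters with a list median of at least 1 held 12.4% of DMSO cells (11.6 to 13.3) and 13.9% of RO-3066 cells (12.8 to 15.0), and a further cluster with a median between 0 and 1 held 8.97% and 6.14%. With the list kept, the shares were 6.58% and 11.5%, so the size of this class depends on whether the genes under comparison take part in the clustering.

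The same gene groups differed between the libraries inside the clusters defined on DMSO cells. Across the 8 such clusters with at least 100 cells of each library, the megakaryocyte median was between 0.21 and 0.72, the p53 target median between 0.03 and 0.93, the stem cell median between 0.08 and 0.56, the erythroid median between 0.17 and 0.63, the neutrophil and monocyte median between 0.23 and 0.43, the glycolysis median between -0.78 and -0.53 and the histone median between -1.96 and -0.49. The p53 target medians were not taken without the small RO-3066 cluster led by p53 targets. Leaving its cells out lowered the median over all cells from 0.38 to 0.19, so a p53 difference in each cluster apart from those cells is not shown. Treml1 was higher in RO-3066 in 8 of 8 clusters (log2 1.09 to 1.98), as were Itga2b (0.30 to 1.201) and Gata1 (0.19 to 1.16), and Pf4 was lower in all 8 (-0.74 to -0.07). G2 and M phase genes were higher in 3 clusters and lower in 5 (-0.49 to 0.54). The cluster that was megakaryocyte-like by Ppbp, Clec1b, Ly6g6f and Serpine2 had a median of 83964.5 UMIs per cell in DMSO and 86295 in RO-3066.

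**Figure D3:**
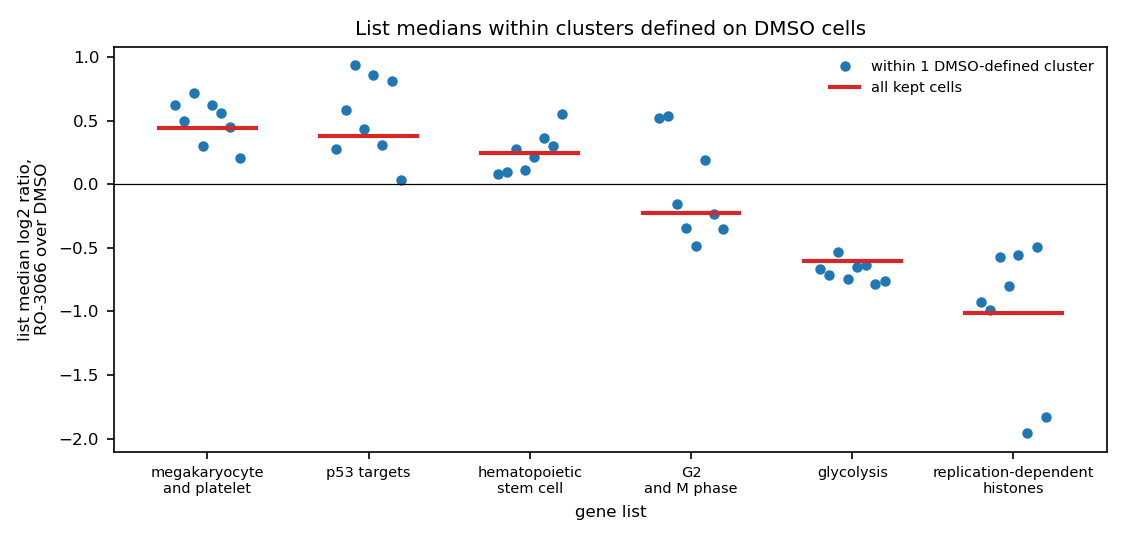
Median log2 ratio of CPM in RO-3066 over DMSO for 6 gene lists (vertical axis). Each blue point is 1 of the 8 clusters defined on DMSO cells that held at least 100 cells of each library, and red lines are the medians over all kept cells; megakaryocyte and platelet medians run from 0.21 to 0.72 and glycolysis medians from -0.78 to -0.53.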

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

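The setting with all barcodes kept was planned beforehand. The test of UMIs per cell within clusters was written before its result was seen, but its range of UMIs was chosen after the data were seen. All other tests in this part were chosen after the result was seen. So were the comparison of those clusters with and without the UMI range and the sizes that drew attention to a phase difference (0.1 for a list and 0.3 for a gene). Of the RO-3066 barcodes 2.16% (1.73 to 2.67) were left out by the cell filter against 0.422% (0.276 to 0.618) of the DMSO barcodes, which drew attention because these barcodes are outside the reported comparisons. They numbered 84 in RO-3066, 62 of them with over 10% mitochondrial UMIs, and 26 in DMSO. With all barcodes kept, likely doublets included, 34 genes were at least 2-fold higher and 39 lower, and the megakaryocyte median was 0.47.

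Some cell cycle genes differed between the libraries in opposite directions by phase call, and none of these gaps was tested. Phase calls are made from the S phase and the G2 and M phase lists themselves, so the cells compared under a call are picked on these genes and need not be alike. The S phase list median was -0.11 in cells called S and 0.23 in cells called G2M, a gap of -0.34, and the G2 and M phase median was 0.30 and -0.47, a gap of 0.77. Plk1 had 23.9 CPM in RO-3066 and 16.4 in DMSO in cells called S (log2 0.51) and 56.5 and 127 in cells called G2M (log2 -1.15), a gap of 1.67. Hmmr had log2 ratios of 0.32 and -1.18, a gap of 1.497, and Pimreg of 0.30 and -1.15, a gap of 1.45.

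Megakaryocyte and platelet genes were higher in RO-3066 (median log2 0.44), and within the 8 DMSO-defined clusters so were the medians of the erythroid (0.17 to 0.63) and the neutrophil and monocyte lists (0.23 to 0.43), although over all cells Tfrc of the first and Prtn3 of the second were lower, so the difference is not shown to be particular to megakaryocyte genes. The median outside the megakaryocyte-like cluster was 0.57 (0.43 to 0.76). This does not decide against a larger number of such cells as the whole cause. That cluster took 425 RO-3066 cells, while a megakaryocyte-like cluster of both libraries together held 561, so some lie outside it. In the 6 clusters with low megakaryocyte genes, Pf4 was at 412 CPM in RO-3066 and 568 in DMSO. Removal of the library mean until no Pf4 was left gave the other members a median of 0.77 (0.50 to 1.26). Removal of RNA of the megakaryocyte-like cluster gave 0.79 (0.52 to 1.23). These medians argue against free RNA of those 2 makeups as the whole cause. Free RNA of another makeup stays open. Pf4 in the barcodes left out was at 888 CPM in RO-3066 and 13964 in DMSO. Of these barcodes 62 of 84 in RO-3066 and 20 of 26 in DMSO had over 10% mitochondrial UMIs, so they need not stand for free RNA. In cells of 15000 to 40000 UMIs, the 5 clusters with enough cells, all low in these genes, had medians of 0.28 to 0.45 with a middle value of 0.37 against 0.45 to 0.72 without that limit, and 0.29 and 0.28 in the clusters where RO-3066 cells in the range had fewer UMIs than DMSO cells (0.872 and 0.915 of the DMSO median), so UMIs per cell are not the whole cause there but may account for a part. For the value over all cells UMI content cannot be told apart from other causes: the median over all cells of that range was -0.037 (-0.20 to 0.22), but the range held only 11 RO-3066 and 50 DMSO cells of the megakaryocyte-like cluster. Of the lineage lists, only the megakaryocyte list was put to these tests of free RNA and UMIs per cell. Over all cells the intervals over members were -0.14 to 0.91 for the erythroid and -0.45 to 0.73 for the neutrophil and monocyte median. As a hypothesis, culture with RO-3066 may go with higher levels of part of the genes of several blood lineages, megakaryocyte genes among them. This would hold in cells given to clusters low in megakaryocyte genes. With 1 library each, any other difference between the cultures or libraries stays open.

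A cluster found with both libraries together held 186 RO-3066 cells (5.05% of that library) and 9 DMSO cells (0.154%) and was led by p53 targets, which define it and are no separate finding; as these genes differ between the libraries, the shares are not read as a difference in a cell type. Against the other RO-3066 cells, 31 p53 targets had a median log2 ratio of 2.82, with Cdkn1a at 485 against 37.4 CPM and Mdm2 at 170 against 24.9, while the megakaryocyte list median was -0.73. Its median UMIs were 0.679 (0.591 to 0.792) of those of the other RO-3066 cells, lower but above the third set as the limit for low quality, and its median mitochondrial share was 1.98% against 1.68%. Doublets hold the RNA of both cells, so these lower UMIs argue against them as well, and 2.66% (0.869 to 6.10) of the matching cluster with doublets kept were called doublets against 3.13% of the other RO-3066 cells, which by itself decides nothing. The values are consistent with a p53 response in a small part of the RO-3066 cells, a hypothesis found and tested on the same libraries, and nothing here tells whether the compound or the culture set it off.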

How the results depend on the processing

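The settings that leave out the megakaryocyte-like cells or the p53-target-rich cluster, the UMI ranges and the clustering without the megakaryocyte list were chosen after the data were seen. The stem cell list median stayed between 0.17 and 0.38 and the p53 target median between 0.19 and 0.97, and the megakaryocyte median was above 0 under each alternative except 1. Where values moved or turned, the cause was not tested. Genes at least 2-fold higher and lower, 34 and 39, numbered 22 and 23 with equal weight per cell, 102 and 67 in cells called G1, 5 and 13 at 100 CPM or more, and 201 and 65 with no minimum. In other settings only 1 of the counts changed by more than a factor of 1.5. With thinned cells, where this was the lower count, they were 25 higher and 23 lower. It was the higher count in the rest: 21 and 27 with a pseudocount of 5, and 121 and 58 at 5 CPM or more. Without the megakaryocyte-like cells the counts were 18 and 27, and in the middle 50% of cells by UMIs 22 and 43. The G2 and M phase median was -0.32 with median-ratio scaling, -0.0037 with equal weight per cell, 0.013 with thinned cells and 0.20 in cells called G1. The S phase median was -0.21 in cells called G1 and -0.12 in the middle 50% by UMIs. With equal weight per cell and with thinned cells, Mki67 turned to 0.16 in both and Lmo4 to 0.015 and 0.0086; Pf4 turned to 0.058 with phases weighted equally, and Mdm2 to -0.032 without the p53-target-rich cluster.

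In cells called G1, 86 of them in RO-3066, the megakaryocyte median was 1.07, and the erythroid, lymphoid and interferon medians turned to -0.14, -0.028 and -0.012. Genes that turned there were Plk1 (0.29), Top2a (0.86), Pf4 (1.51), Slc6a13 (-0.077), Hbb-bt (-0.43), Nkg7 (-0.37), Lyz2 (-0.065), Lmo4 (0.068), Bcl11a (-0.088), Rfc2 (-0.13), Hmmr (0.42), Cdkn2d (0.76), Ifi47 (-0.17), Nfkbia (-0.048), Nfkb1 (-0.13) and Map1lc3a (-0.19). In cells of 15000 to 40000 UMIs, the megakaryocyte median turned to -0.037, Cdk1 to -0.10, Vwf to -0.16, Gp1bb to -0.73, Gata1 to -0.83, Klf1 to -0.073, Treml1 to -0.13, Nkg7 to -0.38, Lmo4 to 0.14 and Bad to -0.011. Of 1482 gene values over all settings, 31 turned, as given here, 871 moved beyond counting error with their direction kept and 580 did not.

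G2M calls were 60.0% in DMSO when thinned to 5000 UMIs, 70.5% in DMSO and 83.5% in RO-3066 when thinned to 20000, 82.0% in RO-3066 without thinning, and 55.1% and 76.3% with a score limit of 0.1. The RO-3066 share above the megakaryocyte score limit was 35.1% at the 75th and 11.8% at the 95th percentile, and 12.9% with phases weighted equally. The DMSO share was not taken with that weighting, so 12.9% is not to be set against the 10.0% of all DMSO cells. By phase call, DMSO and RO-3066 shares were 1.51% and 8.14% in G1, 8.19% and 9.04% in S, and 11.8% and 21.4% in G2M. The shares of DMSO and RO-3066 cells in megakaryocyte-like clusters, 3.03% and 15.4% with both libraries clustered together, were 9.12% and 11.9% at resolution 1.2, 4.82% and 8.64% with cell cycle genes kept, 6.58% and 11.5% with DMSO cells clustered alone, and 12.4% and 13.9% when the megakaryocyte list was also left out. The DMSO share was 0.0171% at resolution 0.5 and 6.33% with doublets kept. Clusters with a list median between 0 and 1 held a further 12.3% of DMSO and 14.9% of RO-3066 cells with both libraries together. At resolution 0.5 such clusters held 30.8% and 15.9%. The shares thus depend on the limit of 1 and are not read as a difference between the libraries. No paired analysis was possible because each group has 1 library. Depth limits the genes below about 5 CPM most, such as Procr and Mpo.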

Other observations

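The tests of phase makeup, cell makeup, UMIs per cell and hypoxia-inducible factor targets were chosen after the result was seen. Interferon response genes had a median of 0.33 (percentile 100) in RO-3066 over DMSO, with 6 of 22 at least 1.5-fold higher and none at least 1.5-fold lower, among them Trim30a at 1.98-fold and Ifi47 at 1.59-fold, while in the 86 RO-3066 cells called G1 the median was -0.012 and Ifi47 was lower (log2 -0.17). Autophagy and lysosome genes had a median of 0.24 (percentile 100), with the autophagy receptor gene Sqstm1 at 1.55-fold and the hexosaminidase gene Hexa at 1.54-fold. Of the NF-kB and inflammatory cytokine list 7 genes were measured, with a median of 0.56 (percentile 99.4), Nfkbia at 1.497-fold and Nfkb1 at 1.22-fold, which were lower in cells called G1 (log2 -0.048 and -0.13). The autophagy and lysosome list and the NF-kB list were higher in RO-3066 in 8 of 8 DMSO-defined clusters, at 0.15 to 0.39 and 0.27 to 0.64. The unfolded protein and integrated stress response list had a median of 0.03 (percentile 84.7), but the transcription factor genes Ddit3, Atf5 and Atf4, which act in the integrated stress response, were 2.69-fold, 2.45-fold and 1.42-fold higher, and Ddit3 was higher in 8 of 8 clusters (log2 0.91 to 1.53).

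Medians of the immediate early (0.12, percentile 88.1), heat shock and chaperone (0.06, percentile 94.1), JAK-STAT (0.07, percentile 77.8) and actin, tubulin and motor (-0.01, percentile 91.4) lists lay inside the middle 95% of matched random lists; within the last, Vim was at 0.583-fold and Flna at 1.44-fold. Mitochondrial genome transcripts had a median of 0.10 (percentile 98.4), with mt-Nd1 at 1.29-fold and mt-Atp8 at 0.638-fold. Outside the rule for named genes, and chosen after the values were seen, the genes at least 4-fold lower were Dlk1, Egln3 and Scin. Dlk1, which encodes a Notch-like membrane protein, had 1.32 CPM in RO-3066 and 29.4 in DMSO (log2 -3.71), Scin 7.02 and 37.6 (log2 -2.27) and Egln3 6.05 and 33.1 (log2 -2.28).

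Glycolysis genes were lower in RO-3066 (median log2 -0.61), and Egln3, Bnip3, Slc16a3 and Pdk1 are known targets of hypoxia-inducible factors. The values argue against phase makeup, since the highest median within a phase call was -0.62. They also argue against UMIs per cell, since the median among cells of 15000 to 40000 UMIs was -0.88 (-0.98 to -0.43). The highest median in a DMSO-defined cluster was -0.53, which argues against the shares of those clusters as the whole cause. RO-3066 cells were given these clusters by their nearest DMSO cells and need not be like them, so a finer makeup of cell types stays open. Lower activity of these factors may be a cause, but the data do not settle it: of 19 measured targets outside the glycolysis list the median was -0.59, yet 10 of them, such as Egln3, Bnip3, Ankrd37 and Plod2, were listed after their low values had been seen or were anticipated, which fixes that outcome in part. The other 9 had a median of -0.12 (-0.52 to 0.16), at percentile 6.78 of matched random lists, with Bhlhe40 at -0.97 and Ndrg1 at 0.72. A difference in cell density or oxygen between the cultures stays open, as the labels give neither.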
